A study of Mus musculus with 16 samples.

How the data were processed

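RNA of cells sorted from dissociated olfactory mucosa was hybridized to Clariom S mouse arrays (Affymetrix). The 24 mice, of both sexes and 7 to 12 weeks old, carried the S100a5-tauGFP reporter and were pooled in 8 pools of 3, of which 4 received the odor and 4 filtered air. Animals stayed in chambers for 40 h under an air flow of 3.1 L/min, and from 26 h on the stimulus was pulsed for 10 s every 20 min. Each pool gave 1 GFP+ and 1 GFP- sample, labelled as biotinylated cRNA from 50 to 100 ng of total RNA, which makes 16 arrays in 4 groups of 4. The odor is named 1-pentanethiol in the series title and the sample labels and bourgeonal in the series' design text, and the sample labels were followed.

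The deposited values are log2 signals of probe sets, for which the processing notes of the submitters name Affymetrix Expression Console. Its version, the summarization and normalization algorithm, and whether other arrays were normalized together with these are not given in the sources used here. The table covers 28846 features with values from 2.51 to 18.85, of which 22206 probe sets outside the control classes were tested; 19572 of these carry 1 gene symbol and 2634 none. The controls comprise 5222 negative control, 1324 positive control, 63 spike-in and 31 other entries, which were used for checks alone. No further scaling or filter was applied for the values in the report. The negative control entries had a median of 6.26, which was taken as the level of nonspecific signal. It is not the lowest level of the tested probe sets, whose first quartile had group means of 5.29 to 5.40. The number of arrays limits the precision.

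The 4 group means were fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation (total degrees of freedom 16.66), and 5 comparisons were taken from the fit: GFP+ against GFP- in the vehicle pools, the same in the odor pools, odor against vehicle in GFP+ and in GFP- cells, and the difference of the GFP+ minus GFP- differences. Tests were two-sided, and a Benjamini-Hochberg adjusted p under 0.05 over the tested probe sets of a comparison was the threshold. No block was used. Pairing was checked by correlating the deviations of arrays from their group means across probe sets: GFP+ and GFP- arrays of a pool, which come from the same mice, correlated with r from 0.0119 to 0.224. Arrays with the same replicate number in the odor and vehicle groups correlated with r from 0.186 to 0.29 in GFP- and from 0.0311 to 0.256 in GFP+ cells, and were over 0.1 for every pair in GFP- cells but not in GFP+ cells, so the number was taken to pair samples in GFP- cells alone. The Y-linked genes went with the number in both fractions, which come from the same pools, so pairing in GFP+ cells is not excluded. Values from fits without a block do not take such pairing into account. Fits with the pool or the replicate number as a block were run as alternatives.

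30 gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, adjusted over the 30 lists of a comparison. With the preset correlation 41 results passed, and 14 of them also passed with an estimated correlation; fry asks whether a list's genes move on balance in a direction, without comparing them with other genes. The lists were odorant receptors, class I odorant receptors, trace amine-associated receptors, vomeronasal receptors, immediate-early genes, slow activity-dependent genes, axon guidance, mature neurons, olfactory transduction, immature neurons, globose basal and cycling cells, horizontal basal cells, sustentacular cells, Bowman's gland and respiratory epithelium, microvillar and solitary chemosensory cells, ensheathing glia, macrophages and other leukocytes, neutrophils, lymphocytes, erythroid, endothelial and fibroblast cells, guanylate cyclase D neurons, heat shock, unfolded protein response, xenobiotic defence, sulfur and thiol metabolism, ribosomal proteins, the respiratory chain, and sex-linked genes. Odorant receptors were the probe sets with a symbol of Olfr and a number. Class I receptors, 119 on the array, were taken as families up to MOR42, a rule chosen after the annotation was seen, when the current receptor names it was to use were found to be missing. The gene annotation supplied with the series served for names, families and neighbours, and no positions are given.

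The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined, except where stated. Genes with 1 symbol were named per comparison as the up to 12 highest and 6 lowest odorant receptors, and the up to 8 highest and 8 lowest other genes, among those past the threshold whose groups did not overlap. Where fewer than 5 passed, the 5 with the smallest p were considered and said not to pass. Up to 4 passing members of each list past the camera threshold were added, and S100a5, Omp, Kirrel2, Fos, Gap43 and Cyp2g1 always; Xist and Ddx3y were to be named as well but have no named probe set here. Predicted genes and clone names were left out, and of the genes under the rule those that describe each comparison are printed.

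The alternatives were quantile normalization, array medians set equal, odorant receptor medians set equal, leaving out the dimmest 25% of probe sets, a variance trend with robust moderation, array weights, only the arrays of the compared groups, leaving out each replicate, the pool as a block or a random effect, and the replicate number as a block. A pseudocount on the linear scale was planned and not used, since the values are log2 already. The fit was tested on simulated data of 22206 probe sets with 200 changed, 50 for each size: of changes of 1, 2, 3 and 4 on the log2 scale, 23, 42, 50 and 50 were called in the difference of differences, with 6 unchanged probe sets called. In the other comparisons 36 or 37 of 50 changes of 1 and at least 49 of 50 larger changes were called, with 6 to 17 unchanged probe sets called. The simulated noise was independent between arrays and probe sets, without ties by pool or replicate number. These counts check the fit and do not give its error rate on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.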

Results

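Olfactory mucosa of S100a5-tauGFP mice was dissociated and sorted into GFP-positive (GFP+) and GFP-negative (GFP-) cells after the animals had been exposed to the odorous thiol 1-pentanethiol or, as vehicle, to filtered air. S100a5 encodes a calcium-binding protein whose transcript in olfactory sensory neurons depends on their activity, so the reporter marks neurons that were recently active. An olfactory sensory neuron expresses mainly a single odorant receptor gene, and the design, known as the Kentucky assay, looks for receptors whose transcripts become enriched in GFP+ cells with an odor. The 16 arrays came from 8 pools of 3 mice, 4 pools per stimulus, with 1 GFP+ and 1 GFP- array from each pool. The series' design text names bourgeonal, a different odorant, whereas its title and every sample label name 1-pentanethiol, and the odor is called by the name in the sample labels here.

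Signal was measured as log2 values for 22206 probe sets, 1080 of them for odorant receptors. The median of all probe sets was 7.75 ± 0.03 and 7.76 ± 0.02 on the GFP- arrays of the odor and vehicle pools, and 7.43 ± 0.03 and 7.41 ± 0.03 on their GFP+ arrays (SD, n = 4 each). Correlations across probe sets ran from 0.984 to 0.995 between arrays of a group and from 0.949 to 0.971 between a GFP+ and a GFP- array. On the GFP+ array of vehicle pool 2 the negative control entries had a median of 7.28, against 6.22 to 6.38 on the other vehicle GFP+ arrays. Differences below are on the log2 scale, ± SE from the model, with n = 4 arrays per group, and adjusted p-values are from limma unless camera is named. The number of arrays limits the precision.

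The sort was described first, as the difference of GFP+ from GFP- cells without the odor and with it. S100a5, the gene behind the reporter, was higher in GFP+ cells by 0.87 ± 0.12 in the vehicle pools (1.83-fold, adjusted p = 3.51e-05) and by 0.99 ± 0.12 in the odor pools (1.99-fold, adjusted p = 7.79e-06). Among the most depleted transcripts, Ly6c2, a surface antigen of myeloid cells, differed by -9.19 ± 0.25 in the vehicle pools and -8.39 ± 0.25 in the odor pools, and the neutrophil granule protein genes Lcn2 and Ngp by -8.45 ± 0.45 and -8.38 ± 0.40 in the vehicle pools. Odorant receptors went both ways, with 399 of 1080 higher and 264 lower in GFP+ cells of the vehicle pools and 396 higher and 294 lower in those of the odor pools. Omp, the classical marker of mature olfactory neurons, lay near the top of the measured range (18.32 in GFP+ and 18.27 in GFP- cells of the vehicle pools) and differed by 0.05 ± 0.10 and 0.03 ± 0.10, short of the threshold, with the sign turning with receptor medians set equal. With array medians set equal it passed as higher, by 0.40 and 0.36 (adjusted p = 0.0026 and 0.00505).

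Among receptors of the vehicle pools, Olfr481 (5.43 ± 0.34, 43.1-fold, adjusted p = 3.49e-09), Olfr613 (5.29 ± 0.39), Olfr309 (4.95 ± 0.31), Olfr110 (4.83 ± 0.34) and Olfr536 (4.81 ± 0.27) were the most enriched in GFP+ cells. Olfr1384 (-6.15 ± 0.66, adjusted p = 1.74e-06), Olfr1507 (-6.05 ± 0.82) and Olfr677 (-5.56 ± 0.56) were the most depleted. In the odor pools the highest were Olfr110 (5.80 ± 0.34, 55.8-fold, adjusted p = 1.91e-09), Olfr481 (5.30 ± 0.34) and Olfr1093 (5.06 ± 0.22), and the lowest were Olfr677 (-6.23 ± 0.56), Olfr1384 (-6.09 ± 0.66) and Olfr99 (-5.77 ± 0.47). In at least 1 sort the lower group of Olfr481, Olfr613, Olfr677, Olfr1384, Olfr1507, Ly6c2, Mki67, Jchain, Trpm5, Egr1, Akap3, Nell2 and Galnt15 lay within 1 SD of the negative control median of its arrays or under it, which limits what their sizes show. For Olfr1507, Olfr1384 and Egr1 in the vehicle pools this came with a wide spread (8.30 ± 2.00, 7.31 ± 1.91 and 7.78 ± 1.37, SD, against 6.55), so these sizes are imprecise. The sorts of the vehicle and odor pools share no array, but the fit gave both the same estimate of the spread per probe set. Their calls are therefore not fully independent. Higher in both were 345 receptors, where 146.3 are expected of independent lists. Lower in both were 243 (71.87 expected), and 4 passed in opposite directions. Across the 1080 receptors, which are not independent replicates, the enrichment of the vehicle pools and of the odor pools correlated with r = 0.945 (Spearman's rho = 0.928). Adjusted over the list alone, 734 receptors passed in the vehicle pools and 752 in the odor pools. The 119 class I receptors, the family of fish-like receptors, had a median of 0.46 in the vehicle pools (camera adjusted p = 0.00744), with 41 higher and 13 lower, but an adjusted p = 0.658 with an estimated correlation. In the odor pools their median was 0.25 (camera adjusted p = 0.954).

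Outside the odorant receptors, the genes most enriched in GFP+ cells of the vehicle pools included Fxyd2, a regulator of the sodium pump (3.32 ± 0.30, 9.96-fold, adjusted p = 2.41e-07), and the trace amine-associated receptors Taar4 (2.80 ± 0.27), Taar9 (2.18 ± 0.43) and Taar7b (1.49 ± 0.31). Of the 15 trace amine-associated receptors, 7 were higher and 5 lower, and the list as a whole did not pass (camera adjusted p = 0.3). Ptprn, a protein of dense-core vesicles, the sperm-associated anchoring protein gene Akap3, Pcp4l1 and Nell2 were higher by 1.58 ± 0.15, 1.49 ± 0.21, 1.48 ± 0.15 and 1.40 ± 0.27. In the odor pools Fxyd2 (3.05 ± 0.30), Taar4 (2.31 ± 0.27), Ptprn (1.79 ± 0.15) and Taar9 (1.65 ± 0.43, adjusted p up to 0.0606 over all alternatives) were again higher, with Pcdh10, a protocadherin (1.84 ± 0.39), and Galnt15, a glycosyltransferase gene (1.79 ± 0.25).

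Genes known to depend slowly on neuronal activity were higher in GFP+ cells: 7 of 10 in the vehicle pools (list median 0.84, camera adjusted p = 0.000367) and 6 of 10 in the odor pools (1.01, camera adjusted p = 0.000413). With an estimated correlation the list had adjusted p = 0.151 and adjusted p = 0.156. Pcp4l1, Lrrc3b (1.34 ± 0.42 and 1.37 ± 0.42) and Pcdh10 (1.13 ± 0.39 in the vehicle pools) were among them. The calls of Lrrc3b in both sorts and of Pcdh10 in the vehicle pools were lost in some alternatives (adjusted p up to 0.0979, 0.108 and 0.139). S100a5 belongs to this list, and it selected the cells. Kirrel2, an activity-dependent adhesion gene of olfactory axons, was higher by 0.77 ± 0.42 and 0.98 ± 0.42, short of the threshold (adjusted p = 0.206 and 0.103), and passed with each pool of mice as a block (adjusted p = 0.0249 and 0.00732; over all alternatives 0.0249 to 0.49 and 0.00732 to 0.225). Immediate-early genes had negative list medians of -0.90 in the vehicle pools and -1.03 in the odor pools, with 15 and 14 of 29 lower. Fos was lower by -4.64 ± 0.70 and -5.06 ± 0.70 and Egr1 by -4.76 ± 0.71 and -4.30 ± 0.71, with camera adjusted p = 2.52e-06 and 1.41e-06 for the list. With an estimated correlation the list had adjusted p = 0.202 and adjusted p = 0.203. Whether these transcripts differed between neurons or came from other cells depleted by the sort was not tested.

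Markers of immature and dividing cells were lower in GFP+ cells. Of 20 measured genes of globose basal and cycling cells, 18 were lower in each sort, with medians of -2.41 and -2.14 (camera adjusted p = 1.41e-20 and 4.04e-18). The proliferation marker Mki67 differed by -5.73 ± 0.31 in both. Gap43, a growth cone protein of immature neurons, was lower by -2.51 ± 0.36 and -2.12 ± 0.36. The immature neuron list had 8 and 7 of 17 lower, with medians of -0.44 and -0.32 (camera adjusted p = 0.000144 and 8.81e-05), although in the odor pools the median turned to 0.01 with array medians set equal. With an estimated correlation it had adjusted p = 0.173 and adjusted p = 0.185. The mature neuron list had 2 and 6 of 24 higher, among them the phosphodiesterase gene Pde1c (0.69 ± 0.10 and 0.60 ± 0.10), with medians of 0.16 and 0.15 (camera adjusted p = 0.0406 and 0.0468). Its vehicle median turned to -0.06 with receptor medians set equal, and it had adjusted p = 0.666 and adjusted p = 0.717 with an estimated correlation, and adjusted p = 0.0559 and 0.0635 with each pool of mice as a block (over all alternatives 0.00402 to 0.666 and 0.00457 to 0.717). Ano2, a chloride channel gene of olfactory cilia on that list, was higher by 0.36 ± 0.11 in the vehicle pools (adjusted p = 0.0327, 0.0695 with the block, and 0.000114 to 0.658 over all alternatives).

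Several other cell types of the mucosa were lower as well. The lists of horizontal basal cells, ensheathing glia, endothelial cells, fibroblasts and stroma, and Bowman's glands did not pass camera in either sort. All but the last had median levels (5.37, 5.53, 5.33 and 6.23) under the negative control median of 6.26. Near that level a depletion may not show, so these results do not say that such cells were kept. All 12 neutrophil genes passed as lower in both sorts, with medians of -7.79 and -7.41 (camera adjusted p = 4.71e-26 and 8.23e-26), and 13 of 17 genes of macrophages and other leukocytes did, with medians of -2.21 and -2.44 (camera adjusted p = 6.44e-14 and 2.18e-16). The leukocyte list had adjusted p = 0.0652 in the vehicle pools with an estimated correlation. Lymphocyte genes had medians of -2.11 and -1.84 (10 and 9 of 10 lower), with the immunoglobulin joining chain Jchain at -7.35 ± 0.35 in the vehicle pools. Erythroid genes had medians of -3.65 and -3.24 (3 of 3 lower), and genes of microvillar and solitary chemosensory cells of -2.37 and -2.53 (11 and 10 of 12 lower), with the channel gene Trpm5 at -4.17 ± 0.34. Genes of guanylate cyclase D neurons, a separate sensory population, had medians of -1.08 and -1.04 (5 and 4 of 8 lower). Whether their transcripts came from that population or from other depleted cells was not tested. These lists passed camera in both sorts, at the highest with adjusted p = 0.000416. Sustentacular cells, the supporting cells of the epithelium, had medians of -0.43 and -0.45 (4 and 6 of 16 lower, camera adjusted p = 0.00328 and 0.00179), with adjusted p = 0.373 and adjusted p = 0.331 with an estimated correlation. Their marker Cyp2g1 differed by -0.63 ± 0.30 and -0.72 ± 0.30, short of the threshold (adjusted p = 0.149 and 0.0922), and passed with each pool of mice as a block (adjusted p = 0.0435 and 0.023; over all alternatives 0.00805 to 0.401 and 0.023 to 0.263). Without the GFP+ array of vehicle replicate 2 the vehicle difference was -0.97 (adjusted p = 0.00805).

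**Figure D1:**
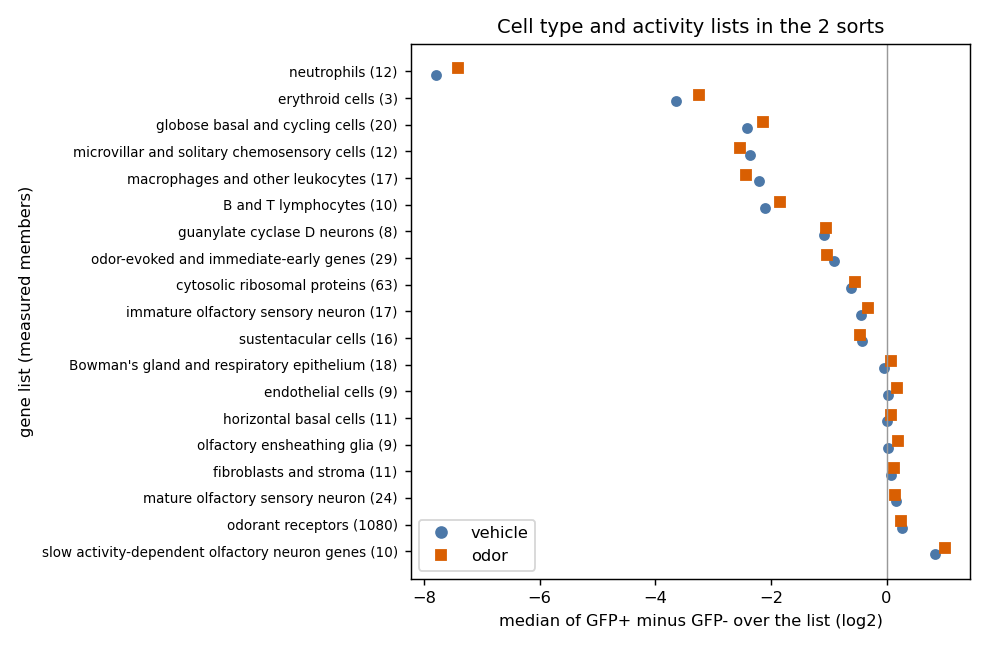
Median log2 difference of GFP+ from GFP- cells over the measured members of 19 gene lists (number in parentheses), in the vehicle pools (circles) and the odor pools (squares). Neutrophil genes lay lowest, at -7.79 and -7.41, and slow activity-dependent genes of olfactory neurons highest, at 0.84 and 1.01.

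Among general cell functions, 46 of 63 genes of cytosolic ribosomal proteins were lower in each sort, with medians of -0.62 and -0.55 (camera adjusted p = 3.02e-18 and 7.25e-17, and adjusted p = 0.0899 and adjusted p = 0.0966 with an estimated correlation). The mitochondrial respiratory chain had medians of 0.17 and 0.16 with 10 of 93 higher and 1 lower (camera adjusted p = 0.0159 and 0.00979), the vehicle median turning to -0.06 with receptor medians set equal, and adjusted p = 0.716 and adjusted p = 0.717 with an estimated correlation. Its member Ndufaf1 was higher by 0.53 ± 0.18 in the vehicle pools (adjusted p = 0.044, 0.0586 with each pool of mice as a block, and 9e-04 to 0.38 over all alternatives). Xenobiotic and oxidative defence genes had medians of -0.21 and -0.09 (7 and 5 of 21 lower, camera adjusted p = 0.0298 and 0.0421), which turned to 0.13 and 0.24 with array medians set equal, and adjusted p = 0.158 and adjusted p = 0.185 with an estimated correlation. Catalase, Cat, differed by -3.36 ± 0.37 and the glutathione transferase gene Gstp1 by -2.10 ± 0.21 in the vehicle pools. Vomeronasal receptors, measured near the floor with a median level of 4.66, had medians of 0.25 and 0.36 with 29 and 58 of 319 higher (camera adjusted p = 0.00102 and 4.63e-06), and adjusted p = 0.1 in the vehicle pools with an estimated correlation. Both calls were lost with quantile normalization (adjusted p = 0.113 and 0.0776), and negative control entries were higher in GFP+ cells by medians of 0.46 and 0.32.

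The remaining lists did not pass camera in either sort. In the vehicle pools, genes of sulfur and thiol metabolism had 5 of 16 lower (median -0.02, mean -0.50, camera adjusted p = 0.0678), axon guidance genes 7 of 24 higher and 1 lower (median 0.21, -0.02 with receptor medians set equal, camera adjusted p = 0.144), and olfactory transduction genes 2 of 21 higher and 2 lower (median 0.12, -0.11 with receptor medians set equal, mean -0.16, test upward, camera adjusted p = 0.784). Genes of Bowman's glands and respiratory epithelium had 1 of 18 higher and 2 lower (camera adjusted p = 0.4), and endothelial genes 1 of 9 higher and 2 lower (camera adjusted p = 0.724). Horizontal basal cells had 1 of 11 higher and 1 lower, olfactory ensheathing glia 1 of 9 lower, heat shock and dissociation stress 1 of 12 higher and 1 lower, and the unfolded protein response 1 of 17 higher and 1 lower, each with camera adjusted p = 0.82. The tests of the glia and unfolded protein lists pointed down beside medians of 0.02 and 0.04, and the endothelial median of 0.02 stood beside a mean of -0.06. Fibroblast and stroma genes (0 of 11 passing) and the Y-linked genes Eif2s3y, Kdm5d and Uty (0 of 3 passing) had camera adjusted p = 0.909, and odorant receptors as a whole 0.199.

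Over all probe sets, 4691 passed in the vehicle pools, 2074 higher and 2617 lower, and 5167 in the odor pools, 2518 higher and 2649 lower. GFP+ and GFP- values did not overlap for 5270 and 5950 of all 22206 probe sets, where chance gives 2.86%. Both sorts had 936 probe sets higher (235.2 expected of independent lists) and 2289 lower (312.2 expected), with the same estimate of the spread behind both lists. The split into higher and lower depended on the scaling. With array medians set equal, which raised the median of all differences by 0.348 and 0.326, 13003 and 13098 were higher and 2008 and 2009 lower; with quantile normalization 3665 and 3594 were higher and 2501 and 2521 lower. With receptor medians set equal, which moved that median by -0.228 and -0.0617, 515 and 865 were higher and 3237 and 2414 lower. Without odor replicate 2, 3340 probe sets passed in the odor pools.

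The question the assay was built for is which transcripts gained enrichment in GFP+ cells with the odor, and it was tested as the GFP+ minus GFP- difference of the odor pools less that of the vehicle pools. On the same arrays this equals the change with odor in GFP+ cells less that in GFP- cells. 14 probe sets passed, and all 14 were odorant receptors with a higher enrichment in the odor pools. Olfr328 gained most, 5.42 ± 0.71 or 42.9-fold (adjusted p = 0.00158), going from -1.74 in the vehicle pools to 3.69 in the odor pools. Olfr195 gained 4.40 ± 0.44 (21.1-fold, adjusted p = 9.95e-05), Olfr224 gained 4.34 ± 0.67 (20.2-fold, adjusted p = 0.0114) and Olfr1183 gained 4.32 ± 0.57 (adjusted p = 0.00158). S100a5 itself did not differ between the sorts beyond the error (0.12 ± 0.17, adjusted p = 0.999).

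The next receptors were Olfr330 (3.37 ± 0.33, 10.4-fold, adjusted p = 9.95e-05), Olfr1193 (3.34 ± 0.37), Olfr1395 (3.12 ± 0.30), Olfr325 (3.05 ± 0.33), Olfr1279 (2.94 ± 0.35), Olfr286 (2.88 ± 0.47, adjusted p = 0.018), Olfr1284 (2.85 ± 0.28) and Olfr1212 (2.83 ± 0.32). The last 2 of the 14, chosen for naming after their values were seen, were Olfr1396 (2.05 ± 0.26, 4.15-fold, adjusted p = 0.00101) and Olfr31 (1.52 ± 0.23, 2.87-fold, adjusted p = 0.00998). Olfr328, Olfr224, Olfr330 and Olfr325 belong to receptor family MOR275, Olfr1279 and Olfr1284 to MOR245, and Olfr1183 and Olfr1193 share MOR230. In each of the 14, which were selected in this comparison, the values of the 4 odor pools lay above those of the 4 vehicle pools. Olfr1395 was depleted from GFP+ cells in the vehicle pools (-2.88) and about even in the odor pools (0.24), whereas Olfr1284 was enriched in both (1.20 and 4.05). For Olfr1183 the mean of the odor GFP- arrays (6.61), and for Olfr1279 those of every group but the odor GFP+ arrays (5.08 to 6.12), lay near or under nonspecific signal, which limits what their sizes show.

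**Figure D2:**
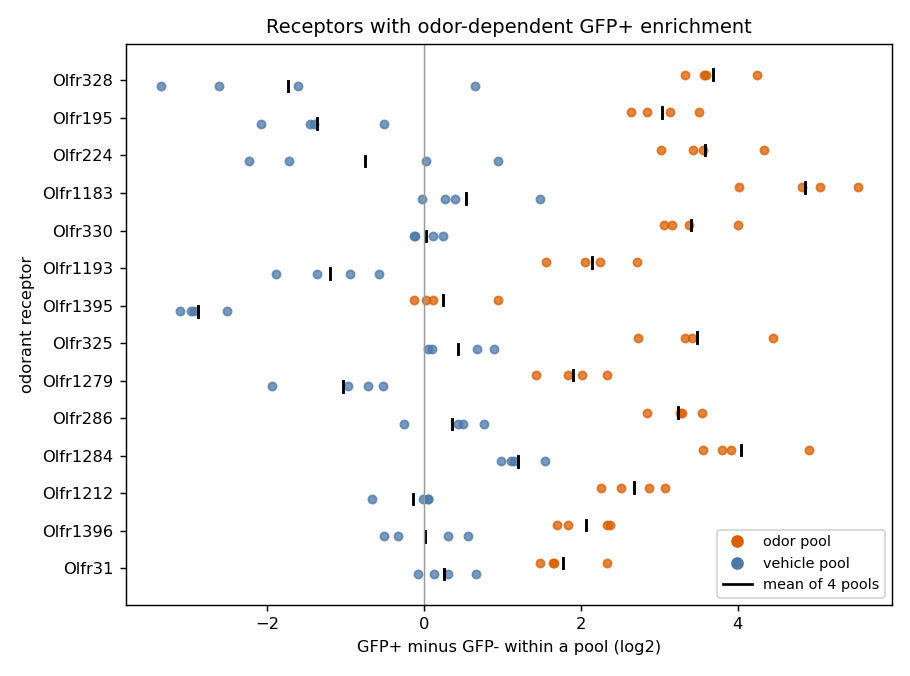
GFP+ minus GFP- difference within each pool (log2, horizontal axis) for the 14 odorant receptors whose enrichment rose with the odor (vertical axis). Points are the 4 odor and 4 vehicle pools and bars their means; the pools of the 2 stimuli do not overlap for any of the 14, and the means of Olfr328 were -1.74 with vehicle and 3.69 with odor.

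By estimate, all 14 receptors were higher with the odor in GFP+ cells and lower in GFP- cells, and the balance varied. For Olfr1395 86.7% of the gain lay in GFP+ cells, and for Olfr1284 8.56%; whether these shares differ was not tested. 7 of the 14 passed in GFP+ cells on their own, 6 in GFP- cells, 0 in both, and Olfr224 in neither. The remaining 1066 receptors did not pass. Adjusted over the list alone, 35 receptors passed, 34 higher and 1 lower. Of the 21126 other probe sets, 0 passed limma, while over all probe sets 1033 had an unadjusted p under 0.05. The smallest p-values among other named genes belonged to Tulp1 (1.07 ± 0.21, adjusted p = 0.112), Mutyh (0.91 ± 0.20, adjusted p = 0.241), Selenom (0.78 ± 0.19, adjusted p = 0.389), Vmn1r60 (-0.95 ± 0.23, adjusted p = 0.389) and Crispld1 (0.75 ± 0.18, adjusted p = 0.42). Omp (-0.02 ± 0.13), Kirrel2 (0.20 ± 0.59), Fos (-0.41 ± 0.99), Gap43 (0.39 ± 0.51) and Cyp2g1 (-0.09 ± 0.42) did not pass either.

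**Figure D3:**
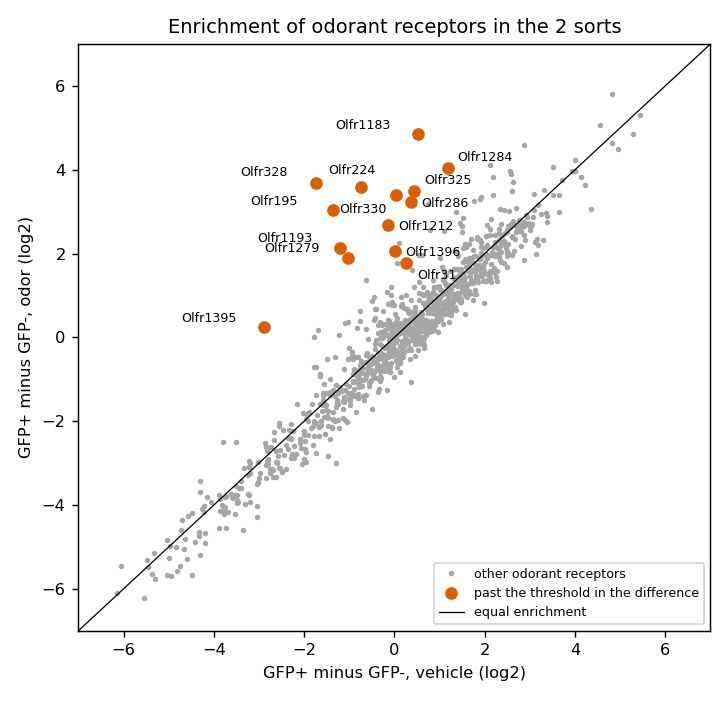
Difference of GFP+ from GFP- cells (log2) for the odorant receptors in the vehicle pools (horizontal axis) and the odor pools (vertical axis), with the line of equal enrichment. The 14 receptors past the threshold (large points) lie above the line, and the enrichment of the sorts correlated with r = 0.945 across receptors.

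Class I receptors had a list median of -0.38 in this comparison (camera adjusted p = 9.69e-09, and adjusted p = 0.993 with an estimated correlation), with 0 of 119 passing on their own. The other lists did not pass; odorant receptors as a whole came closest (median -0.17, camera adjusted p = 0.0657), followed by vomeronasal receptors (median 0.11, camera adjusted p = 0.181). With each pool of mice as a block Olfr31 had adjusted p = 0.0747 and the other 13 receptors kept their call. Olfr224 lost its call without odor replicate 1, 2 or 3 or vehicle replicate 1 (adjusted p from 0.00136 to 0.0902 over all alternatives), Olfr286 without odor replicate 1, 2 or 3 or vehicle replicate 3 or 4 (0.000783 to 0.172), and Olfr31 also without odor replicate 3 or vehicle replicate 2 or 3 (0.00254 to 0.0888). The other 11 receptors kept theirs in all 18 alternatives.

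Within GFP+ cells, the odor was compared with vehicle to see which transcripts of the sorted active cells differed. 17 probe sets passed, all higher with the odor. Pcdh10 rose by 3.99 ± 0.39 (15.9-fold, adjusted p = 0.000122), from 9.72 ± 1.06 to 13.71 ± 0.37 (SD, n = 4). Camk2n1, an inhibitor of calcium/calmodulin-dependent kinase II, rose by 2.68 ± 0.28 (6.41-fold, adjusted p = 0.000165), and Sema7a, a membrane-bound semaphorin, rose by 1.39 ± 0.16 (2.62-fold, adjusted p = 0.000323). Among 9 odorant receptors, Olfr328 rose by 3.17 ± 0.50, Olfr195 by 3.10 ± 0.31, Olfr1395 by 2.71 ± 0.21 and Olfr1279 by 2.37 ± 0.25.

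The other receptors that rose were Olfr1206 (2.05 ± 0.33, adjusted p = 0.0201), Olfr1193 (2.03 ± 0.26, adjusted p = 0.00224), Olfr183 (1.37 ± 0.23, adjusted p = 0.0228), Olfr31 (1.16 ± 0.16, adjusted p = 0.00594) and Olfr1396 (1.04 ± 0.18, adjusted p = 0.0368). Adjusted over the list alone, 16 receptors passed, all higher. The cell adhesion gene Cadm3 rose by 0.92 ± 0.15 (adjusted p = 0.0294), the selenoprotein gene Selenom by 0.80 ± 0.13 (adjusted p = 0.0228), the GTP-binding protein gene Rem2 by 0.76 ± 0.13 (adjusted p = 0.0312) and Crispld1 by 0.73 ± 0.13 (adjusted p = 0.0431). With replicate number as a block Rem2, Crispld1 and Olfr1396 did not pass (adjusted p = 0.0784, 0.0809 and 0.102). The Crispld1 means of 4.53 and 3.80 lay under the negative control medians of 6.36 and 6.55, and it passed in only 2 of 16 alternatives. The vehicle means of Olfr1279 (5.08) and Olfr183 (6.84) were under or near that level too, which limits what their sizes show. 1 probe set without a gene name also passed. For S100a5 the difference was 0.44 ± 0.12 (adjusted p = 0.432), with all 4 odor arrays above all 4 vehicle arrays. The 2 groups did not overlap, in either direction, for 634 of all 22206 probe sets, where chance gives 2.86%. Omp (0.03 ± 0.10), Kirrel2 (0.55 ± 0.42), Fos (-0.30 ± 0.70), Gap43 (-0.10 ± 0.36) and Cyp2g1 (-0.06 ± 0.30) did not pass.

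Of the slow activity-dependent genes, Pcdh10 and Sema7a passed as higher and the other 8 of 10 did not pass, with a list median of 0.40 (camera adjusted p = 1.66e-05, and adjusted p = 0.438 with an estimated correlation). The axon guidance list holds the same pair, which were its 2 passing members of 24 (camera adjusted p = 0.736). Macrophage and other leukocyte genes had a median of -0.31 with 0 of 17 passing (camera adjusted p = 0.000826, and adjusted p = 1 with an estimated correlation), and class I receptors -0.12 with 0 of 119 passing (camera adjusted p = 0.0126, and adjusted p = 1 with an estimated correlation). Over all probe sets 1587 had an unadjusted p under 0.05. Leaving out any pool lowered the count of 17. Without odor replicate 1, 2, 3 or 4 it was 9, 8, 12 and 11. Without vehicle replicate 1, 2, 3 or 4 it was 15, 10, 12 and 7. These fits have fewer arrays, so the drops cannot be laid to particular pools. With only the GFP+ arrays fitted 6 passed, namely Pcdh10, Camk2n1, Sema7a, Olfr195, Olfr1279 and Olfr1395, and these 6 kept their call in all 17 alternatives. The other 11 lost it in at least 1, with Olfr328 and Crispld1 reaching adjusted p = 0.22 and 0.675.

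**Figure D4:**
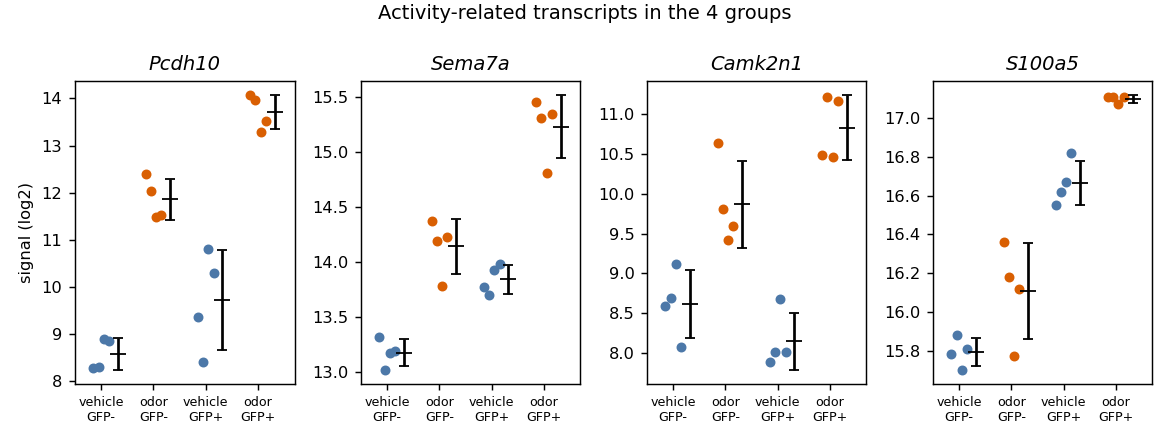
Signal (log2) of Pcdh10, Sema7a, Camk2n1 and S100a5 on each array of the 4 groups, with group mean and SD (n = 4). Pcdh10 rose by 3.99 in GFP+ and 3.28 in GFP- cells with the odor, and S100a5 did not pass in either.

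Within GFP- cells, which hold the other cells of the mucosa and neurons without the reporter, 11 probe sets passed: 9 odorant receptors, all lower with the odor, and 2 genes that were higher. Olfr1183 fell by 4.16 ± 0.40 (adjusted p = 0.00012), from 10.77 ± 0.34 to 6.61 ± 0.84 (SD, n = 4). Olfr1284 fell by 2.61 ± 0.20 (adjusted p = 7.28e-06), Olfr165 by 2.47 ± 0.32 (adjusted p = 0.00273) and Olfr1394 by 2.28 ± 0.36 (adjusted p = 0.0225). The odor means of Olfr1183 and Olfr1394 (5.53) lay near or under the negative control median of those arrays, 6.08, which limits what the sizes of these falls show. Pcdh10 rose by 3.28 ± 0.39 (9.73-fold, adjusted p = 0.000776) and Sema7a by 0.97 ± 0.16 (1.96-fold, adjusted p = 0.0225), as they had in GFP+ cells.

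Olfr330 fell by 2.19 ± 0.23 (adjusted p = 0.000339) and Olfr325 by 2.01 ± 0.23 (adjusted p = 0.000776). The last 3 receptors, named after their values were seen, were Olfr286 (-2.00 ± 0.33, adjusted p = 0.0287), Olfr15 (-1.76 ± 0.28, adjusted p = 0.0225) and Olfr1212 (-1.62 ± 0.23, adjusted p = 0.00632). Adjusted over the list alone, 23 receptors passed, all lower, although the median of all 1080 was 0.10 (camera adjusted p = 0.0322, and adjusted p = 0.805 with an estimated correlation). Class I receptors had a median of 0.21 with 0 of 119 passing (camera adjusted p = 1.96e-08, and adjusted p = 0.805 with an estimated correlation), and globose basal and cycling cells of -0.17 with 0 of 20 passing (camera adjusted p = 0.00782, and adjusted p = 0.805 with an estimated correlation). Slow activity-dependent genes had a median of 0.33 with Pcdh10 and Sema7a as the 2 of 10 passing (camera adjusted p = 8.22e-10, and adjusted p = 0.0768 with an estimated correlation). Camk2n1 (1.24 ± 0.28, adjusted p = 0.301), Mutyh (-0.73 ± 0.14, adjusted p = 0.113) and Havcr1 (0.89 ± 0.21, adjusted p = 0.45) had the next smallest p-values among other genes and did not pass. S100a5 (0.31 ± 0.12), Omp (0.05 ± 0.10), Kirrel2 (0.35 ± 0.42), Fos (0.12 ± 0.70), Gap43 (-0.49 ± 0.36) and Cyp2g1 (0.03 ± 0.30) did not pass.

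Over all probe sets 580 had an unadjusted p under 0.05 in GFP- cells. 7 passed without odor replicate 2 and 7 without vehicle replicate 4, and Sema7a lost its call without odor replicate 1, 2 or 4 or any vehicle replicate, or with only the GFP- arrays fitted (adjusted p = 0.0618; 0.00119 to 0.16 over all alternatives). With replicate number as a block Olfr15 had adjusted p = 0.0755 (0.00117 to 0.167 over all alternatives). Olfr1394 (up to 0.148), Olfr286 (up to 0.185) and Olfr1212 (up to 0.0516) also lost their call without single replicates, and Pcdh10, Olfr1183, Olfr1284, Olfr325, Olfr330 and Olfr165 kept theirs in all 16 alternatives.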

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

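The tests of the explanations below were chosen only after the result was seen, whereas the counts over other splits of the samples were planned.

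Of 120 groups of 4 arrays examined for a sample far from the other 3, 6 stood out, 3 of 28 for array measures and 3 of 92 for named genes, where chance gives about 1 in 20. On the GFP+ array of vehicle replicate 2 the third quartile was 10.75 against 10.89 to 10.92 and the negative control median 7.28 against 6.22 to 6.38. The GFP+ array of odor replicate 3 had an odorant receptor median of 9.516 against 9.736 to 9.754. Among genes, Camk2n1 was 8.676 in GFP+ cells of vehicle replicate 3 against 7.887 to 8.016, Olfr1212 was 12.69 in GFP+ cells of odor replicate 1 against 11.96 to 12.03, and Olfr31 was 12.25 in GFP- cells of vehicle replicate 3 against 12.02 to 12.05.

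For the GFP+ array of vehicle replicate 2, a larger share of all other cell types would raise the markers of each. Of 7 lists of such cells, taking members above nonspecific signal, 2 lay within 0.1 of the group mean, microvillar cells at 0.0614 and lymphocytes at 0.0856, but with 4 members and 1. Sustentacular cells lay at 0.915, neutrophils at 0.413, erythroid cells at 0.331, leukocytes at 0.284 and globose basal and cycling cells at 0.171, so a larger share of all or of sustentacular cells stays open. Higher nonspecific signal was not tested: the gap of its negative control median to the others, 0.844 of the group's range, is the observation itself, so this explanation stays open. No biological explanation was tested.

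The gain in enrichment of 14 odorant receptors is a difference between the sorts of the odor and the vehicle pools. Among the 35 ways of naming 4 of the 8 pools odor, 2 gave as many probe sets as the 14 seen, the real naming included, and the highest other gave 20, so chance is not excluded for the count over all probe sets. Counting receptors alone, 1 of 35 did, with at most 2 under any other naming. This share would exclude chance at 0.05 only if the numbers did not tie the pools. The gain uses the GFP- arrays, where the number was taken to pair samples, so chance is not excluded by this count. For the sorts 1 of 35 splits gave as many as the 4691 and 5167 seen, and the highest other gave 0 in both. For the odor in GFP+ cells 1 of 35 gave as many as the 17 seen, the highest other giving 4. In GFP- cells 2 of 35 gave as many as the 11 seen, the highest other giving 99, so chance is not excluded there. The other naming in both cases set replicate numbers 1 and 3 against 2 and 4, which parts none of the pairs by number; among the 8 splits that part 4 pairs the highest other gave 0 for the gain, the sorts and GFP- cells and 1 for GFP+ cells, and 8 splits are too few for a share under 0.05. A split with 99 probe sets points to a structure of the samples by number. With replicate number as a block 17 probe sets passed for the gain and 12 in GFP- cells.

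Technical explanations were weighed for the 14 receptors. Setting the receptor medians equal shifts each array by 1 constant, and it moved the median gain of all probe sets by 0.166. With gains of 1.52 to 5.42, that 14 of 14 still passed follows from these sizes and adds no test. The small shift itself argues against scaling or the neuron content of the arrays as the whole cause. Sex or batch shared by the pools of a replicate number is balanced by design, since each number occurs once with each stimulus, and no test adds to this: the lowest gain within a number, 0.99 (Olfr31), is above 0 through the selection of the 14. A batch that differed within a number stays open. Probe sets of related receptors could read a common signal: deviations from group means across the 16 arrays correlated with at most r = 0.814 among the 8 same-family pairs (Olfr328 and Olfr224), with a lowest r of -0.124 and a median of 0.371, against a median of 0.22 and a maximum of 0.75 among the 83 other pairs. For Olfr328 and Olfr224 this cannot be told apart from separate responses, since probe sequences were not compared. Of the 14, 6 have no member of the same MOR family among them, but Olfr1395 and Olfr1396 of these 6 are neighbouring genes. A common signal is not excluded for that pair either. A response of the neurons that express these receptors to the odor stays open beside it.

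Pcdh10 and Sema7a rose with the odor in GFP+ and in GFP- cells. GFP+ cells carried into the GFP- fraction would bring their receptors along. The 9 receptors that rose in GFP+ cells had a median difference of -0.569 in GFP- cells, with 1 above 0 and a range from -2.25 to 0.278. Neurons that gain the reporter also leave the GFP- fraction, which would lower the same receptors. These values therefore cannot decide on carried cells. More mature neurons in the odor samples would raise their markers, whose list median in GFP- cells was 0.0201. That list had a median level of 16.62, under a highest value of 18.85, and differed between the sorted fractions by medians of 0.16 and 0.15. It may lie too near the top to show a rise. The 1080 odorant receptors, at a median level of 9.66, had a median of 0.0974 in GFP- cells. This is far under the Sema7a rise of 0.97, which argues against neuron content as the whole cause. Sex or batch shared by a replicate number is balanced by the same design, and the lowest rise within a number, 0.61 (Sema7a), adds no test, since both genes were selected for their rise. Carried cells and a response to the odor in cells without the reporter, which may be a candidate explanation, both stay open. The chamber or handling of the odor pools was not separable from the odor.

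The median of the 119 class I receptors differed between the sorts by -0.3765, past the camera threshold, with adjusted p = 0.993 with an estimated correlation. The values of negative control entries, which belong to no comparison, differed between fractions: 356 of 5222 passed in the vehicle pools (347 higher in GFP+, 6.82%, median 0.461) and 253 in the odor pools (232 higher, 4.84%, median 0.322), against 0 by limma in the other 3 comparisons.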

How the results depend on the processing

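Leaving out the GFP+ array of vehicle replicate 2 was chosen only after the data were seen; the other alternatives were planned. Among the named genes and lists, no call became a call in the opposite direction under any alternative for which the direction was compared. The medians of some lists changed sign with the scaling, as given with their results. For fry only the adjusted p was compared, so a change of direction would not have been seen.

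With odorant receptor medians set equal, 22 probe sets, all 22 odorant receptors, gained enrichment with the odor, against 14, and the 14 were among them. That scaling gave 3279 probe sets in the sort of the odor pools and 17 for odor against vehicle in GFP- cells. Array medians set equal gave 15011 and 15107 in the sorts of the vehicle and odor pools, and array weights gave 19 in GFP- cells. For odor against vehicle in GFP+ cells, fitting only the arrays of the compared groups gave 6 and leaving out the GFP+ array of vehicle replicate 2 gave 10. The cause was not tested; fewer arrays leave less information in the last pair.

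Leaving out a replicate gave 12 to 16 probe sets for the gain in enrichment (12 to 15 receptors), 3735 to 4120 and 3340 to 4136 for the sorts of the vehicle and odor pools, 7 to 15 for the odor in GFP+ cells and 7 to 11 in GFP- cells. With the pool as a block, 14 passed for the gain (13 shared), 4744 (4299 shared) and 5072 (4630 shared) in the sorts. With replicate number as a block, 17 passed for the gain (14 shared), 15 in GFP+ cells (13 shared), where Crispld1, Olfr1396 and Rem2 had adjusted p = 0.0809, 0.102 and 0.0784, and 12 in GFP- cells (10 shared).

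Of the values for named genes, 401 of 411 kept their side of the threshold in the gain of enrichment, 1314 of 1355 and 1223 of 1256 in the sorts, 287 of 373 in GFP+ cells and 257 of 271 in GFP- cells. Tulp1 passed in the gain without vehicle replicate 1 (adjusted p = 0.0491). Of 41 list results, 14 kept their call with an estimated correlation, 35 with fry, 34 with quantile normalization, 38 with array medians and 36 with receptor medians set equal. Vomeronasal receptors, at a median level of 4.66, lie under the negative control median of 6.26, so nonspecific signal limits what their values show.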

Other observations

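The tests on receptor families, neighbouring genes and class I receptors were chosen only after the result was seen.

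The 14 receptors may share families and gene clusters more than random sets of receptors do. They held 8 same-family pairs, against a mean of 0.939 in 100000 random sets of 14 receptors (permutation p = 0.00066, one-sided, adjusted p = 0.0011). Of the 14, 10 lay within 10 receptor genes of another on the same chromosome, against a mean of 2.8 (permutation p = 0.0011, one-sided, adjusted p = 0.0011). Relatives tend to be neighbours, so these are not separate findings, and a signal read in common by related probe sets, with r up to 0.814 between Olfr328 and Olfr224, was not excluded.

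Class I receptors may differ from class II receptors in how their enrichment moved with the odor. The class I minus class II difference of pool medians was -0.133 ± 0.253 in the odor pools and 0.154 ± 0.224 in the vehicle pools (SD, n = 4 each), a difference of -0.287 with an exact permutation p = 0.171, two-sided, so it was not shown with pools as unpaired units. Within each replicate number the odor pool lay below the vehicle pool (0.128 and 0.317, -0.0761 and 0.17, -0.104 and 0.296, -0.48 and -0.167 for numbers 1 to 4). The permutation did not use the numbers, and a paired test was not run.

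In GFP- cells, 99 probe sets passed between replicate numbers 2 and 4 and numbers 1 and 3, 97 higher in numbers 2 and 4 and 2 lower, with 10 of the 29 immediate-early genes among them. No list was tested on this split. The leukocyte list deviated from the group means by 0.215 to 0.419 in numbers 2 and 4 and by -0.639 to -0.104 in numbers 1 and 3, while the neutrophil list overlapped, with 0.0326 to 0.423 and -0.816 to 0.0513. Chosen after their values were seen, Fos ranged from 15.07 to 15.77 against 12.90 to 13.62, Ptgs2 from 9.65 to 10.71 against 6.10 to 6.90, and Osm from 8.66 to 9.70 against 5.71 to 6.49, while Il1b ranged from 12.51 to 13.30 against 9.96 to 10.92, Cxcl2 from 9.06 to 10.32 against 6.17 to 7.45, and Trem1 from 10.48 to 11.50 against 7.35 to 8.44.

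The Y-linked gene Eif2s3y, likewise chosen after its values were seen, was near the floor in pools numbered 3 (4.16 and 4.66 in GFP- and GFP+ cells with odor, 4.77 and 4.51 with vehicle). It was highest in pools numbered 2, at 11.91 and 11.66 with odor and 11.99 and 12.99 with vehicle.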
